A study of Homo sapiens with 48 samples.

How the data were processed

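Cell-free RNA from blood plasma was measured on 48 Affymetrix Human Gene ST arrays. Of these, 44 came from 11 pregnant subjects, each sampled in trimester 1, trimester 2, trimester 3 and immediately post partum, and 4 came from 4 non-pregnant donors. The authors labelled the cDNA with biotin by the array maker's standard procedure, per the labels' protocols. The deposited table holds 1 value per probe set and array on a log2 scale. The log base was inferred from the values, which ran from 1.458 to 14.132, and is not given in the sources used here. MAS5 is named as a tool per the submitters' processing notes, without a version. Its role is unclear, because this array type carries no mismatch probes. The background correction, the summarization of probes and the scaling are not given in the sources used here. The design had assumed linear MAS5 signals, so the deposited log2 values were used without a further log.

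The table held 33297 probe sets. The probe annotation gave 19460 of them 1 gene symbol and 1754 several symbols, and did not list 12083. Only probe sets with 1 symbol were used for genes, and the brightest on average over all arrays stood for a gene with several, which applied to 768 genes. Gene identifiers matched the RefSeq gene table for 19429 probe sets, and 0 symbols needed an update. Probe sets of Y-linked genes and XIST, 24 in all, were removed before any test. Array medians of the deposited log2 values ran from 3.936 to 4.709 and their SDs from 1.709 to 2.321. On the linear scale, the 2%-trimmed means of the arrays ran from 39.31 to 121.59, a ratio of 3.094. This was over the limit of 1.2 set beforehand, so arrays were quantile-normalized. After that, the median of each array was 4.12 and its 60th percentile 4.63. A gene was tested if it lay above the 60th percentile of an array in at least 11 arrays, whatever their group, which kept 10026 of 18394 genes. Levels below the array median lie near the dim end of the scale, where fold changes are understated. The number of arrays limits the precision: the median SE of a log2 fold change was 0.237 between stages and 0.361 against the non-pregnant donors. No 2 arrays held identical values, and correlations between arrays ran from 0.522 to 0.981.

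Stages were compared with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with a term per stage and a term per subject over the 44 arrays, a mean-variance trend and robust moderation. Each stage group was compared with the non-pregnant donors in a fit of all 48 arrays with the donor as a random block, whose consensus within-donor correlation was 0.17. Tests were two-sided, with Benjamini-Hochberg adjustment over the 10026 genes and a threshold of 0.05. The pairing comes from the subject named in the labels. Deviations from the group means correlated with a median r of 0.246 between arrays of 1 donor and 0.0107 between arrays of different donors. By donor, the value ran from 0.0484 to 0.494.

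Gene lists were fixed from textbook knowledge: placenta, fetal hemoglobin, fetal and oncofetal, erythroid, liver, brain, mature neutrophil, neutrophil granule (immature neutrophil), monocyte, T cell, B cell, NK and cytotoxic cell, platelet, interferon response, glucocorticoid response, inflammation, mammary gland, uterus and smooth muscle, endothelium, cell cycle, housekeeping, ribosomal protein, and oxidative phosphorylation. Lists with at least 3 tested members were tested with camera in limma, with a preset correlation between genes of 0.01 and again with an estimated correlation. For the stages, camera kept the subject term. Against the non-pregnant donors it had no donor block, so the arrays of a subject counted as independent. The adjustment ran over 84 tests for the stage comparisons and 63 for those with the non-pregnant donors. For the stages, the mean of a list was also compared within subjects by a two-sided sign-flip permutation test, whose smallest possible p with 11 subjects is 0.0009766. Camera asks whether a list moved relative to the other genes, and the sign-flip test whether its own mean moved.

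Named genes were chosen by a fixed rule. For trimester 3 against trimester 1, post partum against trimester 3 and trimester 3 against non-pregnant, these were up to 10 rising and 10 falling genes with the largest log2 fold change past the threshold and changed that way in at least 9 of 11 subjects. Added were up to 4 called members of each list and CGA, CSH1, PAPPA, PLAC4, CAPN6, ADAM12, KISS1 and HBG2 where measured. For the other comparisons, these were up to 5 rising and 5 falling genes. Where fewer than 5 genes passed, the 5 with the smallest p were named as not passing. Other genes named as examples of lists, across the stages or in all comparisons with the non-pregnant donors were chosen after their values were seen. CSH1 and HBG2 have no probe set with 1 symbol here.

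Principal components of the tested genes showed a split between donors that the labels do not name. The second component held 6.33% of the variance, after 39.7% for the first. It placed 5 subjects and the 4 non-pregnant donors in donor set 1 and 6 subjects in donor set 2, with 46 of 48 arrays on the side of their set. Values within each set are given beside the pooled ones for the means of lists that passed camera. For the comparisons with the non-pregnant donors, called genes named by the rule are given within set 1. The median correlation of an array with the others was under 0.8 for 2 arrays and under 0.9 for 6. Both of the former lay in donor set 2, as did all of the latter except the post partum array of subject D. Donor set and array quality are therefore not independent.

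On simulated data, 200 of 10026 genes were shifted singly, and the further genes of 5 lists by 0.5. The trimester 3 against trimester 1 fit recovered 13.4%, 52.2% and 98.5% of single shifts of 0.5, 1 and 2 on the log2 scale. The recovery was 14.9%, 50.7% and 86.4% for post partum against trimester 3, and 1.49%, 32.8% and 74.2% for trimester 3 against non-pregnant. False calls, counted outside the single shifted genes and the shifted lists, numbered 7, 2 and 3 in these fits. In each, 5 of 5 shifted lists and 0 of 15 unshifted lists were called. The simulated genes varied independently, so this gives no rate of false calls for lists whose genes move together. The simulated trimester 3 against trimester 1 fit made 134 calls, against 0 in the real data, and more calls ease the adjusted threshold. In the real data, PLAC4 differed there by 2.05 (SE 0.47) and MMP8 by 1.94 (SE 0.52). Neither passed (limma adjusted p = 0.144 and 0.444), so the recovery can overstate that of real genes with a large spread. Alternatives covered the scaling, offsets of 1 and 64 added on the linear scale before log2, the filter, the probe sets per gene, the variance model, array weights, the arrays in the fit, the block and leaving out donors. Probe sets with several symbols or none were tested separately. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.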

Results

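The series followed cell-free RNA, the RNA that circulates outside cells in blood plasma, through pregnancy. Each of 11 subjects gave 4 arrays, 1 in each trimester and 1 immediately post partum, and 4 non-pregnant donors gave 1 array each. Values are quantile-normalized log2 signals, and group values are means ± SD. The comparisons ask how plasma transcripts differ between stages within a subject, and between the subjects and the non-pregnant donors.

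Across the 4 stages, 12 of 10026 genes were called as changed. CGA, which encodes the alpha subunit shared by chorionic gonadotropin and the pituitary glycoprotein hormones, had a mean log2 signal of 8.74 ± 1.31 in trimester 1, 6.93 ± 1.28 in trimester 2, 7.35 ± 1.796 in trimester 3 and 3.54 ± 0.21 post partum (n = 11 each, adjusted p = 5.03e-07). PLAC4, a placenta-enriched transcript, stood at 5.21 ± 1.31, 6.58 ± 1.77, 7.26 ± 1.09 and 3.92 ± 0.26 (adjusted p = 6.39e-04). Further placental genes were CSHL1 of the growth hormone and placental lactogen locus and PSG6, a pregnancy-specific glycoprotein. GH1, the pituitary growth hormone gene beside CSHL1, was called as well. Probe sets of CSHL1, GH1 and the PSG family can read near-identical relatives, so the gene of origin is uncertain. Neutrophil genes were MMP8 (neutrophil collagenase), CEACAM8 (a granulocyte adhesion molecule) and CAMP (the antimicrobial peptide cathelicidin). The remaining genes were ALAS2 (the first enzyme of heme synthesis in red cell precursors), DYSF (a membrane repair protein), SERPINB10 (a protease inhibitor) and B3GNT5 (a glycolipid glycosyltransferase). All 12 had their highest mean in trimester 3 except CGA, which had it in trimester 1. The unadjusted p was under 0.05 for 317 genes, where chance alone gives 501. Within donor set 1 the limma fit called 9 genes and within donor set 2 it called 0, and without the 6 arrays that correlated least with the others it called 22. Leaving out 1 subject gave 3 to 15 genes, with 3 without subject A or C and 4 without F.

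**Figure D1:**
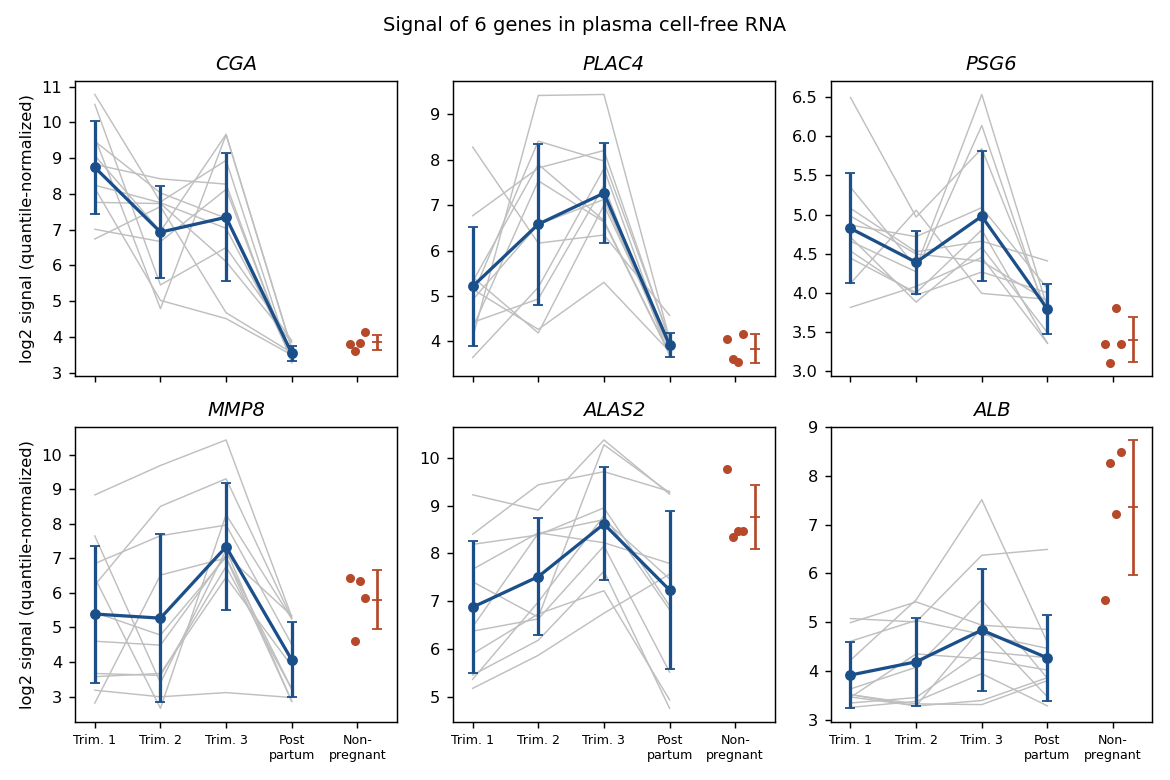
Quantile-normalized log2 signal of CGA, PLAC4, PSG6, MMP8, ALAS2 and ALB by stage, with 1 grey line per subject, the mean ± SD of 11 subjects in blue, and the 4 non-pregnant donors as points beside their mean ± SD. CGA fell from 7.35 in trimester 3 to 3.54 post partum and PLAC4 from 7.26 to 3.92, while ALB stood at 7.35 in the non-pregnant donors.

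Between trimester 1 and trimester 2, no gene passed the limma test (0 called; 218 genes at an unadjusted p under 0.05, against 501 by chance). The smallest p values belonged to MARCHF2, XK, CYB5R3, ISG20L2 and CGA, all with an adjusted p of 0.99979. CGA differed by -1.81 ± 0.50 (log2, SE) and was lower in 10 of 11 subjects. MARCHF2, a ubiquitin ligase, differed by 0.71 ± 0.18 and was higher in 11 of 11, as was XK, a red cell membrane protein, by 0.52 ± 0.15. Neutrophil granule genes rose as a list by 0.26 ± 0.34 (SD over subjects; camera adjusted p = 0.00224; 0.0258 with an estimated correlation), higher in 7 of 11 subjects. Their sign-flip test did not pass (adjusted p = 0.208), and 0 of 17 members passed when adjusted over the list alone or over all genes. The platelet list was higher by 0.56 ± 1.29 in 9 of 11 subjects (adjusted p = 1.54e-08), a call lost at an adjusted p = 0.267 with an estimated correlation. The ribosomal protein list was lower by -0.28 ± 0.81 in 7 of 11 (1.86e-11), lost at an adjusted p = 0.199 with an estimated correlation. In both lists 0 members passed, over all genes or adjusted over the list alone. The trimester 2 array of subject I had the lowest median correlation with the other arrays (0.590), and the SD of the ribosomal protein list in trimester 2 was 0.838 with it and 0.178 without. In donor sets 1 and 2 the granule list differed by 0.23 and 0.28, the platelet list by 0.63 and 0.50 and the ribosomal protein list by -0.02 and -0.51. Without this array, left out after seeing the data, the ribosomal protein list differed by -0.04 ± 0.10 and did not pass (0.261). The platelet list was then higher by 0.82 ± 1.00 (1.95e-13; not passed at 0.108 with an estimated correlation) and the granule list by 0.30 ± 0.34 (0.00250; 0.0437 with an estimated correlation). The trimester 1 array of subject K was the next lowest (median correlation 0.769). Without both arrays, the platelet list was higher by 0.58 ± 0.69 (8.35e-11; 0.192 with an estimated correlation), the granule list by 0.25 ± 0.33 (4.65e-04; 0.0283) and the ribosomal protein list differed by -0.03 ± 0.10 (0.0251; 0.768).

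Between trimester 2 and trimester 3, no gene passed the limma test either (0 called; 449 at an unadjusted p under 0.05). The 5 genes with the smallest p all had an adjusted p of 0.736. MMP8 differed by 2.06 ± 0.52 (SE) and was higher in 11 of 11 subjects, CDKN3, a cell cycle phosphatase, by 2.35 ± 0.55 in 9 of 11, and S100A9, a calcium-binding protein of neutrophils, by 1.07 ± 0.28 in 10 of 11. The others were ZNF275, a zinc finger protein, and ISG20L2, a nuclease. Neutrophil granule genes rose as a list by 0.61 ± 0.49 (SD; camera adjusted p = 7.86e-07; 6.28e-04 with an estimated correlation) in 11 of 11 subjects, with 0 of 17 members called over all genes and 4 higher when adjusted over the list alone. Cell cycle genes were higher by 0.72 ± 0.87 in 11 of 11 subjects (6.21e-06), lost at an adjusted p = 0.0538 with an estimated correlation. Mature neutrophil genes were higher by 0.55 ± 0.86 in 10 of 11 (3.06e-06), lost at an adjusted p = 0.0584 with an estimated correlation. Erythroid genes were higher by 0.38 ± 0.59 in 9 of 11 (4.12e-05), lost at an adjusted p = 0.0538 with an estimated correlation. Ribosomal protein genes were higher on average by 0.22 ± 0.77, although lower in 6 of 11 subjects (3.97e-04), lost at an adjusted p = 0.699 with an estimated correlation. Adjusted over the list alone, 1 of 10 cell cycle, 2 of 14 mature neutrophil, 2 of 22 erythroid and 0 of 62 ribosomal protein genes were higher, and over all genes 0. In donor sets 1 and 2 the granule list differed by 0.45 and 0.75, the cell cycle list by 0.37 and 1.01, the mature neutrophil list by 0.25 and 0.80, the erythroid list by 0.38 and 0.38 and the ribosomal protein list by -0.04 and 0.43. Without the trimester 2 array of subject I, again left out after seeing the data, the ribosomal protein list differed by -0.01 ± 0.15 and did not pass (0.348). The other lists then stood at 0.54 ± 0.46 for granule, 0.47 ± 0.32 for cell cycle, 0.30 ± 0.30 for mature neutrophil and 0.23 ± 0.28 for erythroid genes. With an estimated correlation, all 4 then passed (adjusted p = 1.03e-04, 0.0284, 0.0189 and 0.0284).

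Over the whole of pregnancy, from trimester 1 to trimester 3, neutrophil granule, cell cycle and erythroid genes rose as lists in every one of the 11 subjects. Granule genes, whose products are stored by neutrophils as they mature, rose by 0.87 ± 0.41 (SD; camera adjusted p = 6.40e-16; 4.06e-07 with an estimated correlation). Among 17 members, 12 were higher when adjusted over the list alone, such as CAMP at 1.11 ± 0.25 (SE), MS4A3 at 2.04 ± 0.48, ARG1 at 1.87 ± 0.50 and MMP8 at 1.94 ± 0.52. Cell cycle genes rose by 0.99 ± 0.66 (SD; 2.38e-11; 0.00345 with an estimated correlation), with 8 of 10 higher adjusted over the list alone, such as BIRC5 at 2.00 ± 0.61 and CENPF at 1.54 ± 0.47. Erythroid genes rose by 0.48 ± 0.23 (1.13e-09; 0.00345 with an estimated correlation), with 3 of 22 higher adjusted over the list alone: ALAS2, EPB42 and ANK1, the latter pair parts of the red cell membrane skeleton. Each of these lists reached the smallest possible sign-flip p of 0.0009766 (adjusted 0.00911).

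No single gene passed over all genes (limma, 0 called; 412 at an unadjusted p under 0.05, of which 304 were higher). The smallest adjusted p was 0.0741 for ALAS2, at 1.74 ± 0.33 (SE) and higher in 11 of 11 subjects. SERPINB10 at 1.82 ± 0.37 and B3GNT5 at 1.81 ± 0.37 followed (adjusted p = 0.0790 each; higher in 10 and 9 of 11), then CXCL12, a chemokine, at 0.51 ± 0.11 (0.104, 11 of 11) and CAMP (0.144, 11 of 11). With the values as deposited, 4 genes passed, among them ALAS2, SERPINB10 and B3GNT5. In donor sets 1 and 2 the granule list differed by 0.67 and 1.03, the cell cycle list by 0.69 and 1.24, and the erythroid list by 0.45 and 0.50.

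Placental genes went both ways between trimester 1 and trimester 3. PLAC4 differed by 2.05 ± 0.47 (SE), higher in 10 of 11 subjects, and CSHL1 by 1.13 ± 0.26, higher in 8 of 11, while CGA differed by -1.40 ± 0.50, lower in 8 of 11. Over all genes, none of the 3 passed (adjusted p = 0.144, 0.161 and 0.912). Adjusted over the list alone, PLAC4, CSHL1 and CGA passed at 0.0012, 0.0012 and 0.0479. Over the 16 tested members the mean difference was 0.20 ± 0.49 and the median fold change -0.06, and camera gave an upward direction that did not pass (adjusted p = 0.409). KISS1, a placental peptide precursor, differed by -0.14 ± 0.19. PAPPA, CAPN6 and ADAM12 were too dim for the filter, and without it they differed by 0.21 ± 0.08, 0.57 ± 0.16 and 0.40 ± 0.13, with adjusted p of 0.928, 0.638 and 0.875. Mature neutrophil genes were higher by 0.41 ± 0.46 (SD) in 8 of 11 subjects (8.57e-05), lost at an adjusted p = 0.123 with an estimated correlation, with 0 of 14 members higher adjusted over the list alone. By donor set the difference was 0.32 and 0.48. Platelet genes were higher by 0.42 ± 1.09 in 7 of 11 subjects (5.65e-04), lost at an adjusted p = 0.699 with an estimated correlation, and stood at 0.64 and 0.24 by donor set, with 0 of 26 members higher adjusted over the list alone. Subject K, whose trimester 1 array correlated poorly with the others (0.769), had the largest difference in both lists, 2.35 for platelet and 1.42 for mature neutrophil genes. Without the arrays under 0.8, left out after seeing the data, the platelet list was higher by 0.23 ± 0.93 in 6 of 10 subjects (0.0246; 0.785 with an estimated correlation) and the mature neutrophil list by 0.31 ± 0.32 in 7 of 10 (2.37e-08; 0.0191). The granule, cell cycle and erythroid lists then stood at 0.82 ± 0.39, 0.90 ± 0.63 and 0.48 ± 0.24, each higher in 10 of 10.

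After delivery, 19 genes fell from their trimester 3 level and 0 rose. CGA fell 13.96-fold (log2 -3.80 ± 0.50, SE; adjusted p = 8.98e-05), PLAC4 10.1-fold (-3.34 ± 0.47; 1.70e-04) and MMP8 9.65-fold (-3.27 ± 0.52; 8.69e-04), each in 11 of 11 subjects. The placental genes XAGE2 (-2.00 ± 0.45, lower in 10 of 11) and PSG4 (-1.87 ± 0.36, 10 of 11) fell as well; both belong to families whose members one probe set can read together. CRYAB, a small heat shock protein, fell by 3.13 on the log2 scale (SE 0.62; 10 of 11), and TYMS, which makes thymidylate for DNA synthesis, differed by -2.52 ± 0.51 (9 of 11). B3GNT5 (-1.83 ± 0.37) and SERPINB10 (-1.804 ± 0.37) fell in 9 and 10 of 11 subjects. Adjusted p of these genes lay between 0.0086 for PSG4 and 0.0485 for XAGE2. The post partum means of CGA, PLAC4, MMP8, XAGE2, CRYAB, B3GNT5, SERPINB10 and PSG6 lay under the array median of 4.12, at the dim end where folds are understated.

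As a group, placental genes fell by 0.95 on the log2 scale (SD 0.50; camera adjusted p = 7.71e-13; 0.0115 with an estimated correlation) in 11 of 11 subjects. Subject B, at -0.004, was nearly unchanged. Of 16 members, 6 fell over all genes, which were CGA, PLAC4, XAGE2, PSG4, CSHL1 and PSG6, and 8 when adjusted over the list alone, with XAGE3 and PSG9 added. The list had 48 fixed members, 40 with a probe set and 16 past the filter. CGA, PLAC4 and PSG6 lay under the 60th percentile in every post partum and non-pregnant array, so only the pregnancy arrays kept them. Sizes of difference therefore hold for the tested members, here and against the non-pregnant donors. Over 15 alternatives, no filter among them, the list differed by -1.41 to -0.47 and passed in each. The median member differed by -0.33. KISS1 differed by -0.03 ± 0.19 (SE; adjusted p = 0.993). Without the filter, CAPN6, a calpain-like protein of the placenta, fell by 0.81 on the log2 scale (SE 0.16; adjusted p = 0.0192), and ADAM12 and PAPPA differed by -0.36 ± 0.13 and -0.18 ± 0.08 (adjusted p = 0.697 and 0.950).

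Neutrophil granule genes fell by 1.06 (SD 0.34; 1.82e-21; 2.50e-08 with an estimated correlation). MMP8, DEFA4 (a neutrophil defensin, -2.54 ± 0.50, SE), CEACAM8 (-1.25 ± 0.23) and CAMP (-1.25 ± 0.25) fell over all genes, each in 11 of 11 subjects, and 11 of 17 members fell adjusted over the list alone. Mature neutrophil genes fell by 0.89 (SD 0.51; 2.23e-17; 6.28e-04 with an estimated correlation), with S100A9 called over all genes (-1.26 ± 0.28, 11 of 11) and 8 of 14 adjusted over the list alone. Cell cycle genes fell by 1.03 (SD 0.66; 3.71e-13; 0.00165 with an estimated correlation), with TYMS called over all genes and 8 of 10 adjusted over the list alone. All 3 lists were lower in 11 of 11 subjects, although subject H was nearly unchanged in the cell cycle list (-0.040). Erythroid genes fell by 0.37 (SD 0.32; 6.32e-07; 0.0172 with an estimated correlation) in 10 of 11 subjects, with 0 of 22 called over all genes and 1, ALAS2, adjusted over the list alone. T cell genes were higher by 0.31 ± 0.44 in 9 of 11 subjects (0.0297), lost at an adjusted p = 0.0917 with an estimated correlation, with 0 of 14 members past either adjustment. Monocyte genes differed by 0.09 ± 0.19 and did not pass (0.588).

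**Figure D2:**
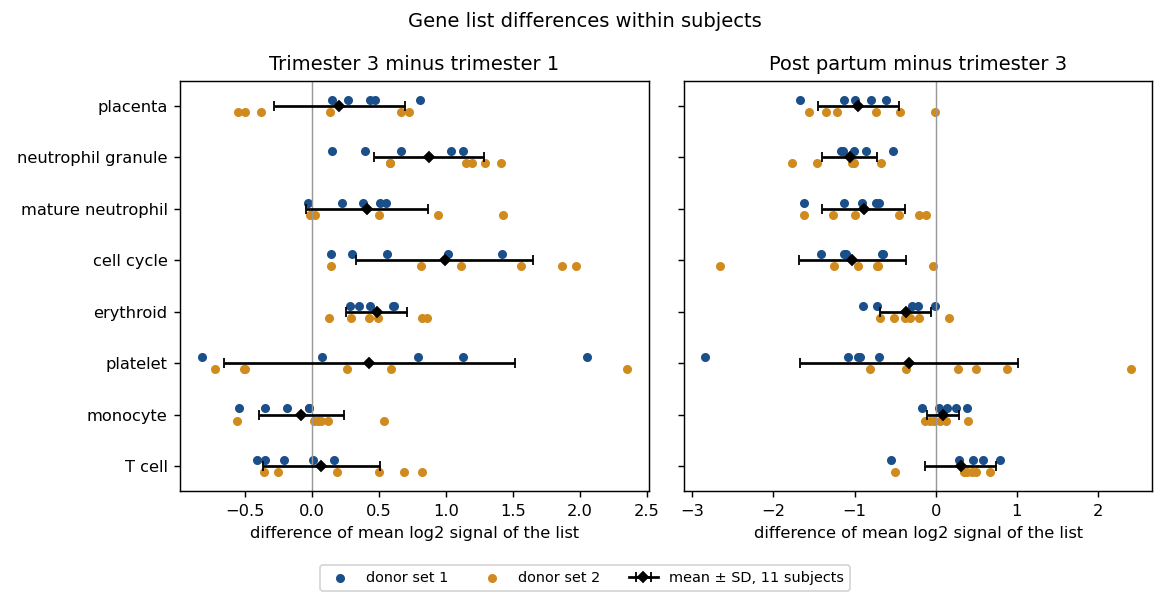
Difference of the mean log2 signal of 8 gene lists within each subject, trimester 3 minus trimester 1 on the left and post partum minus trimester 3 on the right, with points coloured by donor set and diamonds for the mean ± SD of 11 subjects. Granule genes lay above 0 in 11 of 11 subjects on the left and below 0 in 11 of 11 on the right, while monocyte genes had a mean of 0.09 on the right.

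The following genes and lists had the same sign of difference in both donor sets. In sets 1 and 2, CGA differed by -4.57 and -3.16, PLAC4 by -3.42 and -3.28, MMP8 by -3.32 and -3.23, the placenta list by -1.04 and -0.88, the granule list by -0.94 and -1.16, the mature neutrophil list by -1.02 and -0.78, the cell cycle list by -0.99 and -1.06, the erythroid list by -0.43 and -0.32 and the T cell list by 0.31 and 0.31. Limma called 18 genes within set 1 and 0 within set 2, but a difference between the sets passed for 0 genes (482 at an unadjusted p under 0.05). Set 2 held most arrays of low correlation, so donor set and array quality cannot be told apart in these counts. Without the 6 arrays of low correlation 39 genes passed, without subject C 10 and without subject A 11. In fits without 1 subject, the calls of S100A9, XAGE2 and TYMS were lost in 10, 8 and 5 of 11. Platelet genes had no common direction: they differed by -0.33 ± 1.34 over all subjects (0.0142, lost at an adjusted p = 0.745 with an estimated correlation), by -1.30 in set 1 and by 0.48 in set 2. An exact permutation test of that difference between sets gave p = 0.0108, adjusted 0.130 over 12 tests.

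Against the non-pregnant donors, trimester 3 plasma had 28 called genes, 10 higher and 18 lower (658 at an unadjusted p under 0.05). In all comparisons with these donors, counts of subjects are arrays above or below the mean of the 4 donors, not changes within a subject. Placental genes were higher in 11 of 11 subjects: CGA by 3.50 ± 0.72 (log2, SE; adjusted p = 0.0120), PLAC4 by 3.42 ± 0.68 (0.00968), CSHL1 by 1.81 ± 0.38 (0.0152) and PSG6 by 1.58 ± 0.33 (0.0136). The non-pregnant means of CGA (3.84), PLAC4 (3.84) and PSG6 (3.40) lay under the array median of 4.12, where differences are understated. MTND2P28, a nuclear copy of a mitochondrial gene whose probe set can read mitochondrial RNA, was higher by 3.33 ± 0.52 (1.88e-04). Also higher were HSD17B10, a mitochondrial dehydrogenase, the transcription factors TAF10 and USF2, DYSF, and RAB6B, a vesicle transport protein, by 1.10 to 1.89. ALB, which encodes serum albumin and is made by the liver, was lower by -2.52 ± 0.51 (0.0106) in 10 of 11 subjects. The other lower genes of the rule were YAE1 (-3.09 ± 0.68), SLC25A36, a mitochondrial nucleotide carrier (-2.78 ± 0.59), CEP112 (-2.57), SH3D19 (-2.46), GALK2, a sugar kinase (-2.18), CGNL1, a cell junction protein (-2.04), NT5C3B, a nucleotidase (-1.78), JAGN1 (-1.77) and PSMD5, a proteasome chaperone (-1.73), each lower in 11 of 11. KISS1 differed by 0.49 ± 0.27 (0.821).

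The placenta list was higher in trimester 3 by 1.11 (adjusted p = 5.99e-11; 0.0446 with an estimated correlation) in 11 of 11 subjects, with 4 of 16 members called over all genes and 5 adjusted over the list alone. The granule list was higher by 0.82 in 9 of 11 (6.95e-06) and the mature neutrophil list by 0.64 in 10 of 11 (3.31e-04), both lost at an adjusted p = 0.385 with an estimated correlation. The platelet list was higher by 0.61 in 7 of 11 (1.37e-04), lost at an adjusted p = 0.642 with an estimated correlation. The oxidative phosphorylation list was higher by 0.27 in 11 of 11 (0.00310), lost at an adjusted p = 0.597 with an estimated correlation. In the subjects of sets 1 and 2 these lists differed by 1.14 and 1.07 (placenta), 0.60 and 1.01 (granule), 0.78 and 0.52 (mature neutrophil), 1.09 and 0.22 (platelet) and 0.23 and 0.30 (oxidative phosphorylation). Leaving out 1 non-pregnant donor after seeing the data, the placenta list passed with an estimated correlation without the 3rd donor (0.0490) and not without the 1st, 2nd or 4th (0.0884, 0.0961 and 0.0833). Adjusted over the list alone, 1 granule, 1 mature neutrophil, 0 platelet and 0 oxidative phosphorylation genes were higher, and over all genes 0. The camera tests against the non-pregnant donors left the donor block out.

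Within donor set 1, which holds the non-pregnant donors, CGA (4.10), PLAC4 (3.37) and CSHL1 (2.19) passed, while ALB (-1.79, adjusted p = 0.253), MTND2P28 (3.12, 0.0527) and PSG6 (1.68, 0.0551) did not. Of the other genes named above, YAE1 (-2.93), SLC25A36 (-2.60), NT5C3B (-1.79), GALK2 (-1.70), PSMD5 (-1.70), CEP112 (-1.45), DYSF (1.34), RAB6B (1.16) and USF2 (1.06) passed there. SH3D19 (-1.95, adjusted p = 0.0763), CGNL1 (-1.76, 0.0763), JAGN1 (-1.31, 0.359), HSD17B10 (1.36, 0.179) and TAF10 (1.06, 0.153) did not. With donor set as a term, 16 genes passed and ALB did not (-1.83, 0.0763). Leaving out 1 non-pregnant donor left 12, 5, 23 and 4 genes for donors 1 to 4, leaving out subject B left 18, and leaving out the 6 arrays of low correlation left 67. In the fits without 1 non-pregnant donor, the calls of DYSF, HSD17B10, PSMD5, RAB6B and USF2 were lost in 4 of 4 and those of CGA, CSHL1, PSG6, CEP112, JAGN1, SLC25A36 and TAF10 in 3, those of ALB, PLAC4, SH3D19 and YAE1 in 2 and those of CGNL1 and GALK2 in 1, while MTND2P28 and NT5C3B passed in 4 of 4. MTND2P28, whose SD in the non-pregnant donors was 1.92, ranged from 2.55 without the 1st donor to 4.03 without the 2nd, NT5C3B from -2.05 to -1.36 and ALB from -3.15 to -2.14. In fits without 1 subject, JAGN1 lost its call in 8 of 11, USF2 in 6 and DYSF in 5. The median of all genes stood at 0.10 as deposited and 0.03 after quantile normalization, and the folds above are relative to the latter.

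Trimester 1 plasma had 30 called genes against the non-pregnant donors, 6 higher and 24 lower (823 at an unadjusted p under 0.05). CGA was higher by 4.90 ± 0.72 (SE; adjusted p = 5.76e-05), MTND2P28 by 3.38 ± 0.52, SSR2, a protein of the secretory pathway, by 1.96 ± 0.44, HSD17B10 by 1.86 ± 0.42 and PSG6 by 1.42 ± 0.33. ALB was lower by -3.44 ± 0.51 (5.76e-05), SLC25A36 by -3.08 ± 0.59, YAE1 by -2.83 ± 0.68, RSAD2, an interferon-induced antiviral enzyme, by -2.62 ± 0.53 and FHDC1 by -2.52 ± 0.57. All 10 held in 11 of 11 subjects. The differences of CGA and PSG6 are understated here too, because of their dim non-pregnant level. The placenta list was higher by 0.91 in 11 of 11 (6.63e-07), lost at an adjusted p = 0.203 with an estimated correlation. The erythroid list was lower by -0.81 in 11 of 11 (9.03e-05), lost at an adjusted p = 0.551 with an estimated correlation, and the oxidative phosphorylation list higher by 0.25 in 10 of 11 (0.0160), lost at an adjusted p = 0.642 with an estimated correlation. Over all genes, 2 placental, 0 erythroid and 0 oxidative phosphorylation genes were called, and adjusted over the list alone 2, 5 and 0. The 1st non-pregnant donor stood apart in the erythroid list, at 8.21 against 7.19 to 7.34 in the others, and without this donor, left out after seeing the data, the list differed by -0.58 in 10 of 11 (0.0217). Without the 4th donor the oxidative phosphorylation list did not pass (0.22, adjusted p = 0.0635). Without the trimester 1 array of subject K, in a fit without the arrays under 0.8, the placenta, erythroid and oxidative phosphorylation lists differed by 0.82, -0.80 and 0.31. Against all 4 donors, the subjects of sets 1 and 2 differed in the placenta list by 0.72 and 1.06, in the erythroid list by -0.61 and -0.98 and in the oxidative phosphorylation list by 0.28 and 0.23. The fit within donor set 1 called 10 genes, and with donor set as a term 12. In set 1 CGA (5.02), SSR2 (2.14) and SLC25A36 (-2.47) passed, while ALB (-2.89, adjusted p = 0.0621), MTND2P28 (2.90, 0.129), HSD17B10 (1.88, 0.0711), PSG6 (1.53, 0.155), YAE1 (-2.08, 0.262), RSAD2 (-1.81, 0.155) and FHDC1 (-1.96, 0.561) did not. Leaving out the 4th non-pregnant donor left 8 genes and the 3rd 16; without subject K there were 13 and without subject J 18. The calls of HSD17B10, PSG6 and YAE1 were lost in 4 of 4 fits without 1 non-pregnant donor, those of SSR2 and FHDC1 in 3, that of RSAD2 in 2 and that of SLC25A36 in 1. MTND2P28 ranged from 2.61 to 4.08 in these fits. Without 1 subject, YAE1 lost its call in 7 of 11 fits and FHDC1 in 5.

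Post partum plasma had 32 called genes against the non-pregnant donors, 7 higher and 25 lower (800 at an unadjusted p under 0.05). MTND2P28 was higher by 2.85 ± 0.52 (SE), SSR2 by 1.92 ± 0.44, TAF10 by 1.57 ± 0.31, TESK1, a kinase, by 1.496 ± 0.33 and PPP1R2, a phosphatase inhibitor, by 1.18 ± 0.27. ALB was lower by -3.09 ± 0.51 (adjusted p = 6.53e-04), SLC25A36 by -2.87 ± 0.59, YAE1 by -2.87 ± 0.68, RSAD2 by -2.46 ± 0.53 and SH3D19 by -2.34 ± 0.46. Each held in 11 of 11 subjects except MTND2P28, in 10. The placenta list stood at 0.15 and did not pass (0.251). The erythroid list was lower by -0.70 in 9 of 11 (3.31e-04) and the oxidative phosphorylation list higher by 0.29 in 10 of 11 (0.00255), both lost at an adjusted p = 0.597 with an estimated correlation, with 0 members of either called over all genes and 1 and 0 adjusted over the list alone. Without the 1st non-pregnant donor, who stood at 8.21 in the erythroid list, it differed by -0.47 in 9 of 11 and did not pass (0.0621). By set 1 and 2 the erythroid list differed by -0.58 and -0.80 and the oxidative phosphorylation list by 0.34 and 0.25. The fit within donor set 1 called 43 genes, and with donor set as a term 12. In set 1 SSR2 (2.05), TESK1 (1.66), SLC25A36 (-2.74), YAE1 (-2.56) and RSAD2 (-2.04) passed, while ALB (-2.47, adjusted p = 0.0816), MTND2P28 (2.02, 0.211), SH3D19 (-1.66, 0.135), TAF10 (1.33, 0.0654) and PPP1R2 (1.18, 0.0651) did not. Leaving out the 4th non-pregnant donor left 6 genes, the 2nd 17, the 3rd 18 and the 1st 21, and without subject B or J there were 21. The call of YAE1 was lost in 4 of 4 fits without 1 non-pregnant donor and in 5 of 11 without 1 subject, and in the former those of SSR2, TESK1 and PPP1R2 in 3 of 4, those of MTND2P28, TAF10, RSAD2 and SLC25A36 in 2 and that of SH3D19 in 1. MTND2P28 ranged from 2.07 to 3.55 there. Without the 6 arrays of low correlation 82 genes passed.

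The 3 comparisons share the 4 non-pregnant donors and the 11 subjects. Trimester 1 and trimester 3 shared 19 calls, 5 higher and 14 lower, trimester 3 and post partum 16, and trimester 1 and post partum 21. Simulated unchanged groups of the same donors and subjects, with a within-donor correlation of 0.17, shared at most 1, with means of 0.05, 0 and 0 over 20 simulations. The simulated genes did not differ between groups and varied independently, so few could be called and shared. This cannot decide how much of the real overlap comes from the shared people. Independent lists, which leave the shared people out of account, would share 0.00598, 0.00698 and 0.00419 higher calls and 0.0431, 0.0449 and 0.0598 lower ones. With the donors split so that each comparison had its own pair, and the subjects still shared, between 0 and 2, 0 and 1, and 0 and 2 calls were shared, from fits that themselves called between 1 and 20, 1 and 14, and 3 and 20 genes. In all 3 comparisons 14 genes were called, 12 lower and 2 higher, the latter MTND2P28 and TAF10; the lower ones included ALB, NT5C3B, GALK2 and TAF5, a TFIID subunit.

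The other lists passed camera in no comparison. From trimester 3 to post partum, their mean differences were -0.21 for fetal and oncofetal genes, -0.16 for liver, 0.11 for brain, 0.13 for B cells, 0.02 for NK and cytotoxic cells, -0.07 for interferon response, -0.01 for glucocorticoid response, -0.03 for inflammation, 0.07 for uterus and smooth muscle, 0.07 for endothelium and -0.10 for housekeeping genes. Interferon response genes had a mean of -0.07 and a median of 0.04 there. Of the liver genes, 4 were tested, and ALB was the one called against the non-pregnant donors in each comparison. The fetal hemoglobin list had 1 tested gene and the mammary gland list 0, so neither was tested.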

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

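Tests chosen only after the result was seen were those of blood-cell RNA of all kinds, of late pregnancy ended by delivery, of other people or handling in the non-pregnant group, and of PLAC4 against CGA. The division into donor sets was also drawn from these data.

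After delivery, neutrophil granule, mature neutrophil and cell cycle genes were lower than in trimester 3 in 11 of 11 subjects. Low-quality arrays are argued against: in the 9 subjects whose arrays both had a median correlation of at least 0.9, the granule list differed by -1.09 (SE 0.125), against -1.06 in all. The donor set with the smaller difference still showed -0.94 (SE 0.119), which argues against a single set as the source. Mature neutrophil genes differed from the mean of monocyte and T cell genes by -1.09 (SE 0.150) in 11 of 11 subjects. The values of these lists were known when they were chosen. They argue against a loss of RNA that is equal in all blood cells. Erythroid genes also differed by -0.37, and platelet genes by -1.30 in donor set 1 and 0.48 in set 2. A loss shared by only some other blood cells stays open. A biological difference between the stages stays open and was not tested, and cell counts were not analysed here.

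Of the 28 genes called in trimester 3 against the non-pregnant donors, 24 are not on the fixed placenta list; where their transcripts are made was not tested. Within donor set 1, the median absolute log2 fold change of the 28 genes called in trimester 3 was 1.41 (SE over the genes 0.166). Over all subjects it was 1.75, so a part played by donor set 2 stays undecided. The 24 called genes outside the placenta list moved back post partum by a median of 5.97% of their distance from the non-pregnant level (SE over the genes 4.57). Both SEs treat genes as replicates and measure no spread between people. The genes were called for their distance from 4 donors, which can overstate that distance and understate the percent. The 4 placental genes, called the same way, moved back by 92.7%. For most of the 24, this argues only against a source that ended at once with delivery as the main source of the distance. Plasma was taken immediately post partum, so an effect of pregnancy that fades more slowly stays open. DYSF (102%) and RAB6B (60.9%) moved back furthest, 24.6% or less being the value for the other 22. For these 2, a source that ended at once with delivery stays open. As a median, the 24 kept 94.0%, so other people, or other collection and handling, in the non-pregnant group cannot be told apart from lasting effects of pregnancy, because no subject was sampled before or long after it and only 4 donors stand on the other side.

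Between trimester 1 and trimester 3, the change of PLAC4 minus that of CGA within a subject was 3.45 (log2, SE 0.664), above 0 in 10 of 11 subjects. As deposited it was 3.36, and in donor sets 1 and 2 it was 3.00 and 3.83. Subject K of set 2, whose trimester 1 array correlated poorly with the others (0.769), had the largest difference. There PLAC4 went from 3.64 to 7.80 and CGA from 10.5 to 6.50. A change of all placental RNA together, or of the array scaling, moves both genes alike. The difference only combines both changes given above, from a pair chosen after they were seen. It argues against such a change as the whole source for this pair alone. Neither gene passed over all genes on its own, and no biological explanation was tested.

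FHDC1 stood out in the non-pregnant donors, with 1 donor at 9.86 and the others between 7.61 and 7.92, a gap of 0.866 of the range. The mean of the erythroid list did so too, at 8.21 against 7.19 to 7.34, a gap of 0.851. Of 32 such groups, 2 exceeded Dixon's critical value, where chance gives about 1.6.

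Probe sets with no or several gene symbols, which entered no comparison above, held further differences. Of 4856 tested, 21 were called in trimester 3 against the non-pregnant donors, 20 of them higher. From trimester 1 to trimester 3, 7 were called, 2 higher and 5 lower, and 6 of these 7 carry several symbols.

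Chance assignment of the same arrays was tested with 100 splits for each count, the real one included. Stages were reassigned within subjects for the counts between stages. For those against the non-pregnant donors, the 15 arrays of the compared groups were split anew within the fit of all 48 arrays. For the 12 genes across the stages, 2 splits gave as many, and the highest other gave 20, more than the real count; that share is under 0.05. For the 19 genes from trimester 3 to post partum, 1 split gave as many, the real one, and the highest other gave 12. The 30, 28 and 32 genes of trimester 1, trimester 3 and post partum against the non-pregnant donors were each matched by 1 split, the real one. The highest others there were 3, 3 and 5. For the 19, 30, 28 and 32, no other split gave as many genes, and the share was under 0.05. This argues against chance assignment of the arrays for these counts. It does not exclude chance, because the shares were not adjusted over the counts. Against the non-pregnant donors, a split could also place a subject's array in the non-pregnant group while other arrays of that subject stayed in the fit. Such a group is not made up of separate donors. The 12 met the same bound, but 1 other split gave more genes. Chance is not excluded for the 12 either. A count of 0 is matched by every split whatever the data, so the 100 of 100 for each of the 3 comparisons between trimesters, with 1 as the highest other, decide nothing.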

How the results depend on the processing

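Scaling, offset, filter, probe sets per gene, variance model, array weights, arrays in the fit, block, estimated correlation and left-out donors (for counts) were fixed before the data were examined. Leaving out arrays of low correlation or the trimester 2 array of subject I, the donor sets, and left-out donors for single genes and lists were chosen after seeing the data. Apart from left-out donors and that array, named genes kept direction and side of the threshold in 847 fits, lost the call in 133, gained one in 15 and reversed in 4; leading lists kept it in 235, lost it in 14 and reversed in 1; counts stayed within 1.5-fold in 78 and moved in 41. Where a count moved, the cause was not tested, except that fits on fewer arrays or genes have fewer of them. Dim signals limit fold changes: 8 named genes, CGA and PLAC4 among them, lay under the array median post partum.

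Stages together (12 genes) became 6 with an offset of 64, 37 with array weights, 20 and 22 without arrays of correlation under 0.8 and 0.9, and 0 within donor set 2. Trimester 3 against trimester 1 (0 genes) became 4 as deposited (4 higher), 1 with an offset of 64, 1 with the stricter filter, 15 with array weights, 4 and 5 without low-correlation arrays, and 1 within donor set 1. Post partum against trimester 3 (19) became 48 with array weights, 30 and 39 without low-correlation arrays, and 0 within donor set 2.

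Trimester 1, trimester 3 and post partum against non-pregnant (30, 28 and 32) became 79, 81 and 86 with an offset of 64 (4 higher and 75 lower, 7 and 74, 7 and 79), 14, 15 and 16 with the stricter filter, 81, 131 and 153 with array weights, 13, 18 and 8 with only the groups compared, and 12, 16 and 12 with donor set as a term. Without a filter the latter 2 became 44 and 49, without arrays under 0.8 they became 56 and 51, and under 0.9 67 and 82. Within donor set 1 the first became 10. As deposited, calls split 3 higher and 29 lower in trimester 1 (6 and 24 otherwise) and 4 and 36 post partum (7 and 25).

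With no replicate block, that is without pairing by subject, 5 genes passed across the stages, 7 from trimester 3 to post partum and 17 for trimester 1 against non-pregnant; no other count moved over 1.5-fold. Of the named genes, 15 calls were lost without the block, MMP8 after delivery among them (-3.27, adjusted p = 0.0918).

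Leaving out 1 subject gave 3 to 15 genes across the stages (3 without A or C, 4 without F, 5 without J or K, 6 without E or G, 7 without B or D), 0 to 2 for trimester 3 against trimester 1 (2 without E), 10 to 27 for post partum against trimester 3 (10 without C, 11 without A), and 13 to 42, 18 to 30 and 21 to 40 against non-pregnant (13 without K, 18 without J; 18 without B; 21 without B or J). Leaving out a non-pregnant donor gave 8 to 20, 4 to 23 and 6 to 21, lowest without the 4th. S100A9 lost its post partum call in 10 of 11 such fits and XAGE2 in 8.

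KISS1, never called, reversed from -0.14 between trimester 1 and 3 to 0.0409 with array weights, 0.0292 without arrays under 0.8 and 0.23 within donor set 1, with -0.21 to 0.0319 over left-out subjects (highest without K). After delivery it reversed from -0.03 to 0.0794 within donor set 1, with -0.17 to 0.0568 over left-out subjects (above 0 without E, H or J). Without the trimester 2 array of subject I, the ribosomal protein list reversed in trimester 3 against trimester 2 from 0.22 to -0.0131 and lost its call in trimester 2 against trimester 1, and 6 lists kept theirs. Without both arrays under 0.8 it was -0.0131 and -0.0317, the latter passing (0.0251). Within donor set 1 its mean in the former comparison was -0.0382. Of 40 list fits without 1 non-pregnant donor, 38 kept the call and 2 lost it. The platelet list reversed from -0.33 to 0.48 after delivery within donor set 2. Other list calls lost were those of oxidative phosphorylation in trimester 3 against non-pregnant as deposited (adjusted p = 0.200), of T cells after delivery with an offset of 64 (0.0540), without arrays under 0.8 (0.0572) and in sets 1 (0.307) and 2 (0.126), and of platelets in trimester 3 against trimester 1 in set 2 (0.503).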

Other observations

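DYSF, which seals breaks in the membranes of muscle cells and is also present in neutrophils and monocytes, was highest in trimester 3. Its log2 signal was 4.93 ± 0.54 (SD, n = 11) in trimester 1, 5.29 ± 0.48 in trimester 2, 5.71 ± 0.54 in trimester 3 and 4.54 ± 0.35 post partum, beside 4.56 ± 0.20 in the 4 non-pregnant donors. It fell after delivery in 11 of 11 subjects by 1.17 on the log2 scale (SE 0.17; limma adjusted p = 3.59e-04). It was singled out after its values were seen.

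The 12 genes lower in the subjects at all 3 stages compared with the non-pregnant donors included MECOM, a transcription factor of blood stem cells, FBXW11, a ubiquitin ligase subunit, and RAI14, an actin-binding protein. MECOM differed by -1.52, -1.44 and -1.50 in trimester 1, trimester 3 and post partum (SE 0.33 each), and FBXW11 by -1.66, -1.36 and -1.68 (SE 0.26 each). They were singled out after their values were seen. The 3 comparisons share the same 4 non-pregnant donors, all in donor set 1. Without the 4th donor, the calls in these comparisons fell from 30, 28 and 32 to 8, 4 and 6. Values of these genes within set 1 or without a donor are not given here.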
